A study of Mus musculus with 50 samples.

How the data were processed

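The samples are 50 RNA-seq libraries of double-sorted mouse CD4 T cells, 500 to 1000 cells each, prepared by the low-input protocol of the ImmGen project, per the labels' protocols. The thymus libraries come from the B6.Cg-Foxp3tm1Kuch/J strain and the others, of both arms, from a Foxp3-DTR and GFP strain. The genotype label reads WT for every library, and every mouse is labelled male. The authors deposited 1 table of whole-number read counts per gene symbol for all libraries, with no normalisation. Reads were aligned to mm10 with STAR 2.7.3a and counted per gene with featureCounts, per the submitters' processing notes. The annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Near-identical gene copies and overlapping or antisense genes can therefore share reads, and such counts are uncertain. The table holds 55011 gene symbols, of which 53009, with 99.3% of all counts, match a symbol of GENCODE M21, the mm10 annotation used here for gene positions. The labels' protocols name no molecular identifiers, so counts are taken as reads and not molecules.

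Groups were taken from the labels. The replicate number was taken from the titles. Total counts per library ran from 2521078 to 6981037. Within every group the counts of each pair of replicates differed by more than sampling noise (chi-square per degree of freedom 3.61 to 66.5 over genes with at least 20 counts in the pair), so no library was counted as a duplicate. Whether replicate numbers pair libraries was checked with the correlation over genes of deviations from the group means. Of the comparisons made, only in PBS-labelled ear skin against spleen was it over 0.1 in each same-numbered pair (0.101 to 0.109 in 3 pairs, -0.156 to 0.0585 between different numbers), so there the numbers were taken to pair the libraries, from these correlations and the numbers in the titles alone. DT-labelled liver and spleen, which no test compares but which the pooled DT effect holds together, also met this limit (0.104 to 0.116). To compare numbers of detected genes, every library was thinned to 2521078 counts.

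Each gene was tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3 (two-sided), with TMM normalisation, filterByExpr (minimum count 10, minimum total count 15) and Benjamini-Hochberg adjustment at 0.05. Age and progenitor comparisons used one fit of all 18 thymus libraries. Comparisons of PBS-labelled tissues with spleen and the test of VAT against spleen used one fit of all 32 peripheral libraries. DT against PBS was fitted within each tissue. Levels are TMM-normalised CPM (counts scaled to the library size) with the SD between libraries. Marker sums, detected genes and the plotted VAT levels are plain CPM or counts. Sums of markers of other cell types are given wherever the libraries of 2 compared groups do not overlap, which chance gives in 1 of 10 lists for 3 libraries against 3. SE is the size of the log2 fold change over the square root of F. Log CPM values used a prior count of 2, and several genes near 0 CPM in a group are given as levels. Other folds from such a group are uncertain.

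The 33 gene lists (18 pathways and 15 sets of markers of other cell types, 495 of 498 gene entries in the table), the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where an alternative is said to be chosen after seeing the data. The decision on pairing is another exception. Lists with 5 or more measured genes were tested with camera in limma 3.58.1, with the preset correlation of 0.01, and again with an estimated correlation and with fry. The adjusted p of a list is over the lists of a comparison. The preset correlation gave 51, 29, 46, 47 list calls for age, P2 against P1, DT against PBS and tissue against spleen, and the estimated correlation 13, 8, 0, 21. Named genes are those called with a mean of at least 10 CPM whose 2 groups do not overlap, up to the 10 largest changes in each direction. They also include up to 4 members of a described list with the smallest adjusted p. Foxp3 and Il2ra are always included, with Pparg, Il1rl1, Klrg1, Gata3, Areg, Cd36 and Ikzf2 outside the thymus. For the interactions the limit was 5 in each direction. Gene models named only by a number, pseudogenes and receptor or immunoglobulin segments were left out. Some genes that the rule takes are not reported here.

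The fits were tested on simulated counts with 200 genes of known change, drawn from genes with a mean of at least 10 CPM. Changes in lower genes and data with fewer changed genes were not simulated. At a 2-fold change the edgeR fit recovered 64.0% of the genes for P1 at D49 against D5, 60.0% for VAT against spleen, 68.0% for DT against PBS in VAT and 56.0% in ear skin, and at a 4-fold change 100.0%, 94.0%, 96.0% and 92.0%. The alternatives were other size factors (relative log expression), no filter on low counts, DESeq2 1.42.0, limma voom with quality weights, the compared libraries alone or all peripheral libraries, each replicate left out and the replicate number as a block. Those chosen after seeing the data were a floor of 20 CPM, the share of counts in genes under 1 CPM as a covariate for thymus, leaving out D49 P2 replicates 2 and 3, and a DT effect pooled over the tissues, also fitted with limma voom without and with the replicate number within each arm as a random block (duplicateCorrelation). Python 3.11.15 drew the plots.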

Results

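The series profiled messenger RNA of regulatory T cells (Treg cells), the CD4 T cells that use the transcription factor Foxp3 and restrain immune responses, and of their thymic progenitors in mice labelled male. The question named by the series title is how Treg cells generated around birth seed visceral adipose tissue (VAT), the fat around the abdominal organs. The 50 libraries form 16 groups. In the thymus, 18 libraries cover 2 sorted progenitor populations at day 5, 12 and 49 of life (D5, D12, D49), with 3 libraries in each of 6 groups. P1 cells carried CD25 (encoded by Il2ra) and lacked Foxp3, and P2 cells carried Foxp3 and lacked CD25. The other 32 libraries are Treg cells sorted at 20 weeks of age from spleen, lung, liver and ear skin (3 libraries labelled PBS and 3 labelled DT for each) and from VAT (4 and 4). In the Foxp3-DTR strain Treg cells express the diphtheria toxin receptor, so diphtheria toxin (DT) removes them. Per the series text, mice of 12 weeks received DT on 3 days and rested for 8 to 9 weeks, and the controls were littermates without the receptor. The library titles instead call the control arm PBS, and the genotype label reads WT and the strain label Foxp3-DTR in both arms. Whether Treg cells of the DT-labelled arm were depleted cannot be told from these labels, and the arms are called PBS-labelled and DT-labelled. Each library came from 500 to 1000 cells, with 2521078 to 6981037 counts. The labels do not say that libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

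The first comparison asks how P1 progenitors differ with age. From D5 to D49, messages of cell division and of sterol synthesis fell in P1 cells, and the class I-like genes H2-Q6 and H2-Q7 and the cholesterol exporter gene Abca1 rose. All 27 of 27 measured cell cycle genes fell (median log2 fold change -2.47; camera adjusted p = 1.67e-49, and adjusted p = 0.00568 with an estimated correlation), and 27 fell when adjusted over the list alone. Of the cholesterol synthesis genes, 18 of 22 fell, 20 when adjusted over the list alone, with a median of -1.19 (camera adjusted p = 5.55e-19, and adjusted p = 1.71e-05 with an estimated correlation). Sqle, an enzyme of sterol synthesis, went from 119.7 ± 9.72 to 12.5 ± 3.40 CPM (counts scaled to the library size, mean ± SD, n = 3 in each group here and below unless stated; log2 fold change -3.24 ± 0.26 SE, edgeR adjusted p = 2.48e-08). Among the genes with the largest falls were the ryanodine receptor gene Ryr2 (-5.57), Cd163l1 (-3.98), Crmp1 (-3.34), the asparagine synthetase gene Asns (-3.83) and the centromere gene Cenpn (-3.22), each given as a log2 fold change. The histone genes H3c3, H2bc11 and H2ac11 had log2 fold changes of -3.69, -3.59 and -3.35. In the other direction H2-Q6 (5.50), H2-Q7 (4.88), Abca1 (5.13), the chemokine receptor gene Cxcr3 (4.11), the vomeronasal receptor gene Vmn2r97 (4.94), Tmie (4.23), Insl6 (3.99), Sdc4 (3.96) and Pck2 (3.81) rose. The H2-Q genes are near-identical copies whose reads can be shared. Summed over 1471 olfactory and vomeronasal receptor genes, the D49 P1 libraries held 234 to 335 CPM and the D5 P1 libraries 82.3 to 124. The interferon-induced gene Ifi44 stood at 21 ± 9.36 CPM at D49 and had no counts at D5. In NF-kB, 5 of 16 genes rose, 8 when adjusted over the list alone (camera adjusted p = 4.30e-07, adjusted p = 0.0972 with an estimated correlation). Il2ra stood at 123 ± 18.5 and 121 ± 14.6 CPM (adjusted p = 0.989 with edgeR). Of 14696 genes tested, 1587 changed, 611 higher and 976 lower at D49. The count was 1029 without D5 P1 replicate 1, and Cxcr3 was not called without D5 P1 replicates 2 and 3 (edgeR adjusted p = 0.0721 and 0.0702). Calls were also lost, with the edgeR adjusted p in parentheses, without a filter on low counts for Cxcr3 (0.0677). Sums of markers of other cell types in D49 P1 against D5 P1 were higher for endothelial cells (241 to 258 against 188 to 220.5 CPM), hepatocytes (16.9 to 20.0 against 5.92 to 9.06), macrophages and monocytes (24.8 to 56.8 against 15.8 to 23.6) and NK cells (20.2 to 25.5 against 5.36 to 10.4). Innate-like T cells (5.92 to 10.6 against 16.4 to 22.1) and keratinocytes (11.6 to 12.4 against 18.5 to 24.4) had lower marker sums.

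**Figure D1:**
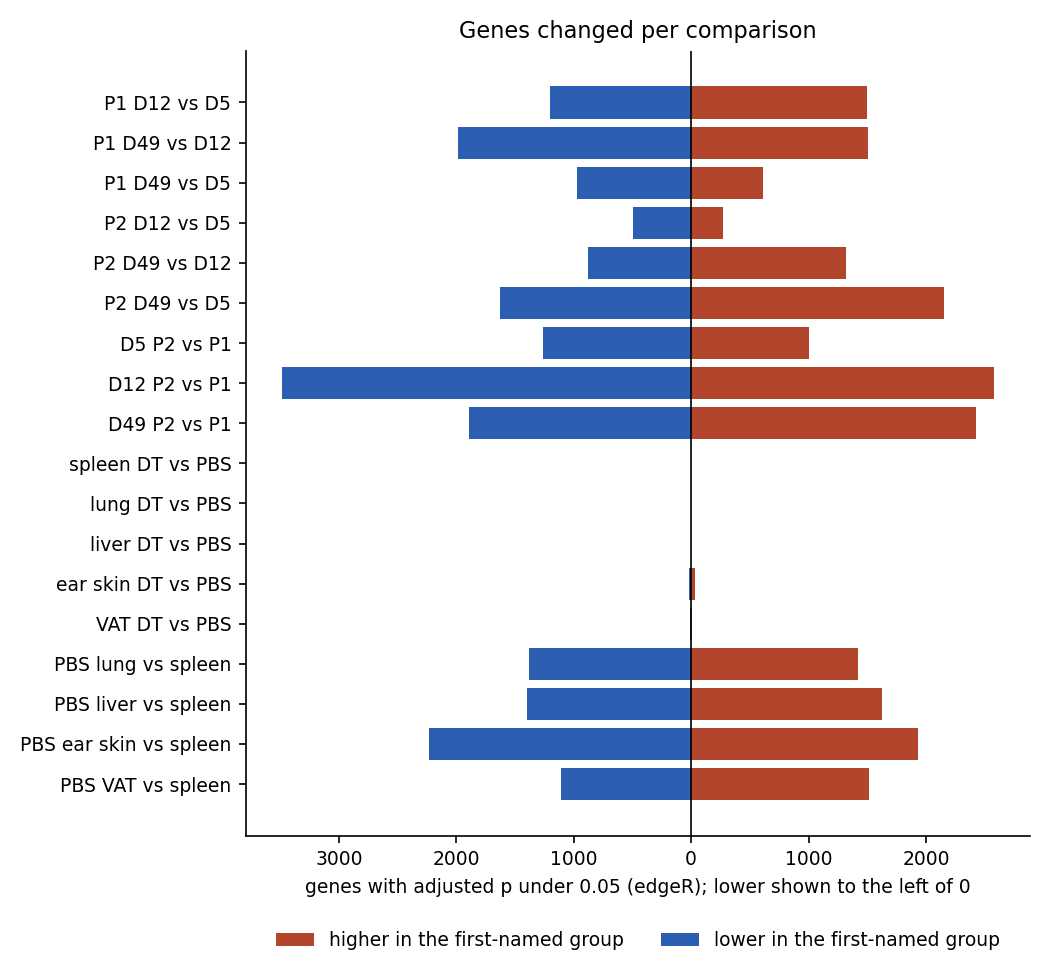
Bars give the number of genes with an edgeR adjusted p under 0.05 in each comparison, those higher in the first-named group to the right of 0 and those lower to the left. The D12 P2 against P1 comparison holds 6068 genes and the spleen, lung and liver DT against PBS comparisons hold 0.

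D12 P1 libraries stood apart in composition. They held 27911 to 31478 detected genes against 20751 to 21283 at D5. Against D5 P1, their sums of markers of other cell types were higher for fibroblasts (7.05 to 12.4 against 0.96 to 3.15 CPM), hepatocytes (28.6 to 30.3 against 5.92 to 9.06) and mesothelial cells (3.06 to 8.99 against 0.55 to 1.18). Innate-like T cell sums were lower (12.1 to 15.8 against 16.4 to 22.1). Sums in D49 P1 against D12 P1 were higher for endothelial cells (241 to 258 against 177 to 224 CPM), macrophages and monocytes (24.8 to 56.8 against 12.0 to 21.6) and NK cells (20.2 to 25.5 against 5.84 to 15.5). B cells (117 to 134 against 148 to 180.1), fibroblasts (1.88 to 2.69 against 7.05 to 12.4), hepatocytes (16.9 to 20.0 against 28.6 to 30.3) and innate-like T cells (5.92 to 10.6 against 12.1 to 15.8) had lower marker sums. So had keratinocytes (11.6 to 12.4 against 17.1 to 32.9) and neutrophils (2.33 to 5.64 against 7.12 to 15.4). From D5 to D12 the long genes Ttn, Ryr3 and Muc16 rose in P1, with log2 fold changes of 5.23, 4.72 and 3.89. From D12 to D49 they fell, with -3.27, -4.22 and -3.01. The genes that fell by D12 include Arglu1 (-3.00), Dpysl2 (-2.92), Pdcd4 (-2.83) and the interferon-induced GTPase gene Irgm1 (-2.55), while Amigo2 (2.87) and Pnrc1 (2.51) rose. From D12 to D49, H2-Q7 (4.37), Cxcr3 (3.88), Cxcr6 (3.03), Art2b (3.61) and Arglu1 (2.87) rose, and Ryr2 (-5.37), the metalloprotease gene Mmp14 (-2.77), E2f8 (-2.71) and Wee1 (-2.71), both of the cell cycle, fell. Cholesterol synthesis fell at each step, with 8 of 22 genes lower at D12 than D5 (10 when adjusted over the list alone; camera adjusted p = 1.27e-07, adjusted p = 0.00236 with an estimated correlation) and 10 lower at D49 than D12 (15 when adjusted over the list alone; camera adjusted p = 2.86e-05, adjusted p = 0.00771 with an estimated correlation). edgeR called 2701 genes from D5 to D12 (1497 higher, 1204 lower) and 3491 from D12 to D49 (1504 higher, 1987 lower). With the share of counts in low genes as a covariate the counts were 448 and 658. This share was 0.90 to 1.86% in D12 P1 and at most 0.34% in D5 and D49 P1, so it cannot be told from age. The first count was 1006, 1199, 1318, 1273 and 1586 without D5 P1 replicates 1, 2 and 3 and D12 P1 replicates 2 and 3, and the second 2241, 2318, 1971, 2129 and 2033 without D12 P1 replicates 2 and 3 and D49 P1 replicates 1, 2 and 3. The balance of higher and lower genes turned with several settings. From D5 to D12 the share of higher genes was 55.4%, but 42.8% with a floor of 20 CPM, 36.2% with the covariate and 40.7%, 41.1%, 45.8% and 48.3% without D5 P1 replicates 1, 2 and 3 and D12 P1 replicate 2. From D12 to D49 it was 43.1%, but 52.0% with a floor of 20 CPM, 53.5% with the covariate and 53.8%, 51.8% and 52.1% without D49 P1 replicates 1, 2 and 3. From D5 to D12, calls were also lost, with the edgeR adjusted p in parentheses, with the covariate for Ryr3, Muc16, Irgm1 and Pnrc1 (0.0570 to 0.157) and with the compared libraries alone for Pnrc1 (0.0912). From D12 to D49 calls were lost with the covariate for Ttn, Ryr3, Muc16, E2f8 and Wee1 (edgeR adjusted p = 0.0722 to 0.248). The covariate and the floor of 20 CPM were chosen after seeing the data.

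**Figure D2:**
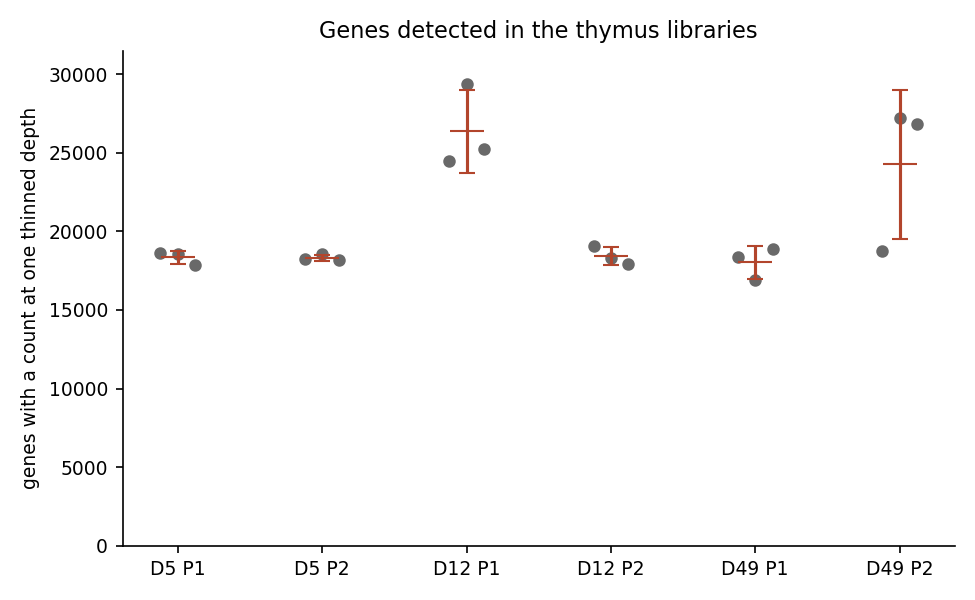
Points are thymus libraries, and the vertical axis is the number of genes with a count after every library was thinned to one depth; the red bar is the mean and SD of 3 libraries. The depth is 2521078 counts, and the D12 P1 libraries and D49 P2 replicates 2 and 3 lie between 24509 and 29372 genes.

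In P2 progenitors cell cycle messages fell with age, and Foxp3 was higher at D12 and D49 than at D5. Cell cycle genes fell from D5 to D12 (27 of 27, median -1.76; camera adjusted p = 1.29e-55, adjusted p = 0.00350 with an estimated correlation; 27 when adjusted over the list alone) and from D5 to D49 (27 of 27, median -3.18; camera adjusted p = 2.02e-35, adjusted p = 0.0208 with an estimated correlation; 27 when adjusted over the list alone). Foxp3 (chromosome X, 7573644 to 7595245, mm10) went from 297 ± 17.9 CPM at D5 to 788 ± 63.5 at D12 (log2 fold change 1.41 ± 0.19 SE, edgeR adjusted p = 8.60e-05) and 434 ± 120.2 at D49. Il2ra, the CD25 gene, rose from 15.7 ± 4.66 to 41.3 ± 7.68 CPM between D5 and D49 (edgeR adjusted p = 0.000122). Of the Treg core list, 8 of 24 genes rose by D12 and 1 fell (15 rose when adjusted over the list alone; camera adjusted p = 3.91e-11, adjusted p = 0.0118 with an estimated correlation). Of the T cell receptor response list, 8 of 19 genes rose and 0 fell (10 rose when adjusted over the list alone; camera adjusted p = 4.15e-08, adjusted p = 0.0127 with an estimated correlation). Cholesterol synthesis fell from D5 to D49 in 17 of 22 genes, 18 when adjusted over the list alone (camera adjusted p = 3.25e-09, adjusted p = 0.000483 with an estimated correlation). Actg2 (4.09), Nrp2 (2.82), Lmo4 (2.38), the transforming growth factor beta-activating integrin gene Itgb8 (2.24), Tcf7l2 (2.22) and Abca1 (2.18) rose by D12, and Cd163l1 (-3.26), Kif18b (-2.56), Mxd3 (-2.41), Trip13 (-2.26) and Ttk (-2.24) fell. By D49, H2-Q6 (5.26), Fgf13 (5.77), Abca1 (4.39), Insl6 (4.21), Vmn2r97 (3.57) and the inhibitory receptor gene Tigit (3.71) had risen over D5, and Ccna2 (-4.79), E2f7 (from 21.3 ± 4.06 to 0.183 ± 0.160 CPM), Uhrf1 (-4.35), Anln (-4.36), Rad54l (-4.25), Crmp1 (-4.37) and Gcat (-6.12) had fallen. Cd163l1 stood at 52.4 ± 12.1 CPM at D5 and had no counts at D49. From D12 to D49 the changes include Foxp3 (-0.86), Crmp1 (-2.47), Kcnf1 (-3.28), Akr1c18 (-3.74), H2-Q6 (2.88) and Fgf13 (2.52). D49 P2 replicates 2 and 3 held 27729 and 28765 detected genes against 19951 in replicate 1. Macrophage and monocyte markers moved with D49 P2: 7 of 8 rose over D5 (7 when adjusted over the list alone; camera adjusted p = 4.91e-06, adjusted p = 0.118 with an estimated correlation), the macrophage lysozyme gene Lyz2 stood at 26.0 ± 20.2 CPM, and the summed markers of the 3 libraries were 102, 223 and 348 CPM. edgeR called 762 genes from D5 to D12 (268 higher), 2196 from D12 to D49 (1317 higher) and 3788 from D5 to D49 (2156 higher). Without both of D49 P2 replicates 2 and 3, an alternative chosen after seeing the data, the last 2 counts were 538 and 1779. With the compared libraries alone they were 79 and 1093. The share of higher genes from D12 to D49 was 60.0%, but 46.2% without a filter on low counts, 47.1% with a floor of 20 CPM, 32% with the covariate, 23.4% without both of D49 P2 replicates 2 and 3 and 44.3%, 41.0%, 46.4% and 44.3% without D12 P2 replicates 1, 2 and 3 and D49 P2 replicate 3. From D5 to D49 it was 56.9%, but 44.6% without a filter on low counts, 48.4% with a floor of 20 CPM, 39.1% with the covariate, 46.1% with the compared libraries alone, 35% without both of D49 P2 replicates 2 and 3 and 45.9%, 47.6%, 45.0% and 48.5% without D5 P2 replicates 1, 2 and 3 and D49 P2 replicate 3. The D12 against D5 count was 446, 462, 441, 435 and 444 without D5 P2 replicates 1, 2 and 3 and D12 P2 replicates 1 and 3. The D49 against D12 count was 885, 703, 951, 5317, 1424 and 1126 without D12 P2 replicates 1, 2 and 3 and D49 P2 replicates 1, 2 and 3, and the D49 against D5 count 2156, 2208, 2232 and 6035 without D5 P2 replicates 1, 2 and 3 and D49 P2 replicate 1. In D49 against D5, Foxp3 was not called without D5 P2 replicates 1, 2 and 3 and D49 P2 replicates 1 and 2 (edgeR adjusted p = 0.123, 0.0868, 0.128, 0.0650 and 0.232). In D12 against D5, Itgb8 and Kif18b were not called without D12 P2 replicate 3 (edgeR adjusted p = 0.0628 and 0.0611). In D49 against D12, Akr1c18 was not called without D12 P2 replicates 1 and 3 and D49 P2 replicates 2 and 3 (edgeR adjusted p = 0.0868, 0.0778, 0.0761 and 0.112). In D49 against D5, calls were also lost, with the edgeR adjusted p in parentheses, without a filter on low counts for Foxp3 (0.145), with the covariate for Tigit and Lyz2 (0.168 and 0.132), with the compared libraries alone for Foxp3 (0.105) and without both of D49 P2 replicates 2 and 3 for Foxp3, Tigit and Lyz2 (0.0908, 0.240 and 0.0912). In D49 against D12, calls were also lost, with the edgeR or, for voom, limma adjusted p in parentheses, with limma voom for Akr1c18 (0.321), with the covariate for Foxp3, Kcnf1 and Akr1c18 (0.331, 0.111 and 0.318), with the compared libraries alone for Foxp3, Kcnf1 and Akr1c18 (0.104, 0.114 and 0.0680) and without both of D49 P2 replicates 2 and 3 for Akr1c18 (0.493). Marker sums of other cell types in D12 P2 against D5 P2 were higher for hepatocytes (12.3 to 17.7 against 4.73 to 11.9 CPM), lung epithelial cells (14.3 to 17.7 against 3.54 to 10.9) and macrophages and monocytes (22.6 to 36.1 against 16.8 to 17.9). B cells (220.1 to 273 against 346 to 384) and neutrophils (0.43 to 0.67 against 1.40 to 2.06) had lower marker sums. In D49 P2 against D12 P2 they were higher for hepatocytes (20.4 to 27.7 against 12.3 to 17.7 CPM), macrophages and monocytes (102 to 348 against 22.6 to 36.1) and NK cells (14.1 to 37.9 against 7.72 to 13). In D49 P2 against D5 P2 they were higher for hepatocytes (20.4 to 27.7 against 4.73 to 11.9 CPM), lung epithelial cells (16.7 to 22.7 against 3.54 to 10.9), macrophages and monocytes (102 to 348 against 16.8 to 17.9) and mesothelial cells (0.86 to 11.3 against 0 to 0.62). B cells (244 to 301 against 346 to 384) had lower marker sums.

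The comparison of P2 with P1 at one age checks the sort and asks how the 2 progenitor populations differ. Foxp3 was higher in P2 at D5, D12 and D49, with 297 ± 17.9 against 11.6 ± 1.3 CPM, 788 ± 63.5 against 8.84 ± 3.43 CPM and 434 ± 120.2 against 14.2 ± 4.16 CPM. Il2ra (chromosome 2, 11642807 to 11693193, mm10) was lower in P2, with log2 fold changes of -2.97, -2.38 and -1.54 (edgeR adjusted p = 6.73e-09, 3.26e-08 and 1.19e-05). Interferon response genes were higher in P2 in 22, 24 and 17 of 28 members at the 3 ages (27, 25 and 18 when adjusted over the list alone). Their camera adjusted p was 5.26e-22, 6.58e-10 and 3.07e-07, and adjusted p = 0.0393, 0.183 and 0.200 with an estimated correlation. Of the naive and recirculating T cell list, which holds Klf3, the genes higher in P2 numbered 11, 11 and 10 of 18 and 4 were lower at each age (adjusted p = 0.0393, 0.139 and 0.223 with an estimated correlation; 11, 11 and 10 when adjusted over the list alone). Cholesterol synthesis was lower in 11, 16 and 7 of 22 genes (11, 16 and 11 when adjusted over the list alone; adjusted p = 0.000308, 0.0197 and 0.0365 with an estimated correlation), and glycolysis in 9, 9 and 9 of 16 (12, 9 and 10 when adjusted over the list alone; adjusted p = 0.0131, 0.139 and 0.0365 with an estimated correlation). At D5 the sialyltransferase gene St8sia6 (3.19), Art2b (3.18), Ly6c1 (3.06), Sntb1 (2.80), Ifit1bl1 (2.71) and Ifi213 (2.58) were higher in P2, and Asb2 (0.216 ± 0.373 against 21.4 ± 2.25 CPM), Chl1 (-4.02), the chemokine gene Xcl1 (-3.18), Bcat1 (-3.00) and the nuclear receptor gene Rora (-2.76) lower. At D12, Art2b (5.58), H2-Q7 (3.53), Flicr (4.74), a noncoding RNA gene at the Foxp3 locus, and Irgm1 (3.39) were higher, and Asb2 (-4.57), Wnt10a (-3.65), Marcksl1 (-3.32) and the polyamine enzyme gene Srm (-3.17) lower. At D49, St8sia6 (3.25), Apoe (2.73) and Neurl3 (2.42) were higher and Bcat1 (-4.90), Pdzk1ip1 (-4.61), Angptl4 (-4.38), Cd24a (-3.89) and the fatty acid-binding gene Fabp5 (-3.72) lower. edgeR called 2258, 6068 and 4318 genes at D5, D12 and D49. With the share of counts in low genes as a covariate the D12 and D49 counts were 3473 and 1827. The D49 count was 2348 without both of D49 P2 replicates 2 and 3. The D49 count was 2805 without D49 P1 replicate 2 and 1220 with the compared libraries alone. At the other ages no single library moved it by over 1.5 times. Markers of other cell types moved with the population. At D5 their sums in P2 against P1 were higher for B cells (346 to 384 against 105 to 161 CPM), endothelial cells (354 to 379 against 188 to 220.5), fibroblasts (3.29 to 5.42 against 0.96 to 3.15) and thymic epithelial cells (26.9 to 31.5 against 13.9 to 21.1). Neutrophils (1.40 to 2.06 against 2.76 to 12.5) had lower marker sums. At D12 they were higher for adipocytes (8.63 to 12.3 against 4.77 to 7.05 CPM), B cells (220.1 to 273 against 148 to 180.1), endothelial cells (373 to 396 against 177 to 224) and macrophages and monocytes (22.6 to 36.1 against 12.0 to 21.6). Dendritic cells (29.6 to 46.2 against 157 to 419), fibroblasts (0.64 to 4.54 against 7.05 to 12.4), hepatocytes (12.3 to 17.7 against 28.6 to 30.3) and mesothelial cells (0 to 1.12 against 3.06 to 8.99) had lower marker sums. So had neutrophils (0.43 to 0.67 against 7.12 to 15.4). At D49 they were higher for B cells (244 to 301 against 117 to 134 CPM), endothelial cells (296 to 385 against 241 to 258), fibroblasts (2.88 to 15.3 against 1.88 to 2.69) and hepatocytes (20.4 to 27.7 against 16.9 to 20.0). Innate-like T cells (10.9 to 21.3 against 5.92 to 10.6), keratinocytes (17.4 to 30.6 against 11.6 to 12.4) and macrophages and monocytes (102 to 348 against 24.8 to 56.8) had higher marker sums.

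Whether the D49 against D5 change differs between P2 and P1 was tested as an interaction. Apoe (3.00), Usp31 (2.45), Tcf7l2 (2.07), Rora (1.82) and Il2ra (1.43) had the more positive change in P2, and Angptl4 (-3.22), Mmp14 (-2.90) and Rad54l (-2.51) the more negative one (differences of log2 fold changes). E2f7 and Enkd1 also had the more negative change in P2, and at 0.183 ± 0.160 and 0.119 ± 0.205 CPM in D49 P2 no fold is given for them. edgeR called 55 genes, 21 more positive and 34 more negative. This count rests on single libraries, being 12, 2, 13, 7, 16, 2, 30, 15, 17, 1243 and 84 without D5 P1 replicates 1, 2 and 3, D5 P2 replicates 1, 2 and 3, D49 P1 replicates 1, 2 and 3 and D49 P2 replicates 1 and 3. Apoe is also on the macrophage marker list, whose messages were higher in D49 P2. Each of these genes lost its call without at least 1 of the libraries. Apoe lost it without D5 P2 replicate 3 and E2f7 without D5 P1 replicate 2 (edgeR adjusted p = 0.0532 and 0.0537), and the others without several. The lost calls had an edgeR adjusted p of 0.0537 to 0.116 without D5 P1 replicate 1, 0.0537 to 0.0966 without D5 P1 replicate 2, 0.0542 to 0.111 without D5 P1 replicate 3, 0.0590 to 0.131 without D5 P2 replicate 1 and 0.0567 to 0.104 without D5 P2 replicate 2. The p was 0.0532 to 0.117 without D5 P2 replicate 3, 0.0501 to 0.0870 without D49 P1 replicate 1, 0.0561 to 0.102 without D49 P1 replicate 2, 0.0538 to 0.0838 without D49 P1 replicate 3, 0.0507 to 0.0578 without D49 P2 replicate 2 and 0.0600 to 0.0693 without D49 P2 replicate 3. Calls were also lost, with the edgeR or, for voom, limma adjusted p in parentheses, with limma voom for Angptl4, Mmp14, Rad54l and Enkd1 (0.0790 to 0.103), with the covariate for all of them (0.0525 to 0.379), with the compared libraries alone for Usp31, Tcf7l2, Il2ra, Angptl4 and Mmp14 (0.0506 to 0.116) and without both of D49 P2 replicates 2 and 3 for Usp31, Tcf7l2, Il2ra, Angptl4 and Mmp14 (0.0539 to 0.245).

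The comparison of PBS-labelled Treg cells between tissues and spleen asks how Treg cells of each tissue differ from those of spleen. In VAT, genes known for VAT Treg cells were higher than in spleen. Pparg (chromosome 6, 115360951 to 115490399, mm10), the nuclear receptor that drives the VAT Treg state, stood at 85.1 ± 16.2 CPM (n = 4) against 0.983 ± 1.54, the interleukin 33 receptor gene Il1rl1 at 988 ± 317 against 23.0 ± 6.17, Klrg1 at 1924 ± 541 against 129 ± 94.6, Gata3 at 2031 ± 442 against 421 ± 146 and the growth factor gene Areg at 656 ± 319 against 4.70 ± 0.489 (edgeR adjusted p = 5.70e-07, 1.34e-09, 4.75e-07, 9.47e-09 and 1.59e-10). The scavenger receptor gene Cd36 stood at 2.36 ± 2.49 against 0.431 ± 0.627 CPM and did not pass (edgeR adjusted p = 0.315). Areg and Il1rl1 were also higher in lung, liver and ear skin than in spleen, with log2 fold changes of 5.74, 6.87 and 6.53 for Areg and 4.03, 4.37 and 4.05 for Il1rl1. Pparg was called higher in liver (1.27 to 8.8 plain CPM) and ear skin (8.60 to 8.94) than in spleen (0 to 3.01). In lung (1.83 to 4.96) it was not called (edgeR adjusted p = 0.105, and 0.00350 without spleen PBS replicate 3). The call in liver was lost without single libraries, spleen PBS replicates 1 and 2 and liver PBS replicates 1 and 2 (edgeR adjusted p = 0.197, 0.149, 0.0650 and 0.263). It was also lost without a filter on low counts (edgeR adjusted p = 0.123), with limma voom (limma adjusted p = 0.166) and with the compared libraries alone (edgeR adjusted p = 0.226). In ear skin the call was lost with the compared libraries alone (edgeR adjusted p = 0.0665). Of the VAT Treg list, fixed before the data were examined, 15, 19, 20 and 21 of 25 genes were higher than in spleen in lung, liver, ear skin and VAT (19, 19, 21 and 21 when adjusted over the list alone; adjusted p = 0.0146, 0.00637, 0.00843 and 0.00178 with an estimated correlation). The effector and tissue Treg list was higher in 26, 28, 27 and 24 of 30 genes in lung, liver, ear skin and VAT (27, 28, 27 and 25 when adjusted over the list alone). Its adjusted p with an estimated correlation was 0.00492, 0.00181, 0.00843 and 0.00194. Interferon response genes were lower in ear skin (25 of 28, median -2.02) and VAT (23, median -1.52), with adjusted p = 0.00843 and 0.00570 with an estimated correlation and 26 and 24 genes when adjusted over the list alone. Naive T cell genes were lower in 17 of 18 in ear skin and 14 in VAT (17 and 14 when adjusted over the list alone; adjusted p = 0.0321 and 0.0222 with an estimated correlation). Genes of the response to tissue digestion moved with the tissues: 10, 15, 12 and 15 of 20 were higher in lung, liver, ear skin and VAT (12, 16, 13 and 16 when adjusted over the list alone; adjusted p = 0.0998, 0.0128, 0.0970 and 0.00526 with an estimated correlation), and in VAT Fos stood at 2456 ± 1049 CPM against 5.35 ± 1.58. Other genes higher than in spleen include Ramp3, Rgs2 and Nr4a2 in lung (7.18, 6.91 and 7.12), Muc1 and Gem in liver (6.16 and 6.5), Pcsk1 and Lmna in ear skin (9.08 and 6.83), and Pcsk1 and Cxcl2 in VAT (9.65 and 9.97). Lower genes include Id3 in lung (-3.98) and liver (-3.00), Gpr83 in liver (-3.19) and ear skin (-6.79), Art2b (0.289 ± 0.302 against 252 ± 89.4 CPM) and the follicle-homing receptor gene Cxcr5 (-6.27) in ear skin, and Usp18 (-3.98), Oasl2 (-4.61) and Dtx1 (-4.16) in VAT. edgeR called 2805, 3023, 4169 and 2627 genes in lung, liver, ear skin and VAT, of which 1424, 1622, 1935 and 1516 were higher. With the compared libraries alone the counts were 1251, 1449, 2263 and 1615. The liver count was 1979 without spleen PBS replicate 1. The share of higher genes in lung was 50.8%, but 48.8% without a filter on low counts and 49.2%, 49.3%, 48.7% and 47.8% without spleen PBS replicates 2 and 3 and lung PBS replicates 1 and 3. In ear skin it was 46.4%, but 53.3% with RLE size factors, 55.7% with DESeq2, 52.9% with limma voom and 51.6% with the compared libraries alone. Spleen PBS replicate 1 stood apart from its group, with Foxp3 at 119.8 plain CPM against 305 and 348 and Il2ra at 837 against 549.6 and 492. Its chi-square per degree of freedom was 52.5 and 66.5 to the other 2, against 16 between them, and its median correlation to its group, 0.897, was the lowest of the 50 libraries. Without it the counts were 2005, 1979, 2921 and 1937 in lung, liver, ear skin and VAT. In ear skin, where replicate numbers were taken to pair the libraries, the keratinocyte and fibroblast marker lists had a camera adjusted p of 0.0616 and 0.122, and of 0.0384 and 0.0384 with the replicate number as a block (adjusted p = 0.191 and 0.554 with an estimated correlation and no block). That pairing was decided after counts with the block had been seen. Markers of other cell types moved with the tissue. Against spleen, their sums in lung were higher for dendritic cells (173 to 210.3 against 86.5 to 158 CPM) and keratinocytes (29.3 to 38.4 against 18.3 to 24.1). B cells (690.3 to 1127 against 1538 to 1942) and lung epithelial cells (9.04 to 18 against 29.6 to 42.0) had lower marker sums. In liver they were higher for dendritic cells (173 to 224 against 86.5 to 158 CPM), hepatocytes (13.9 to 28.2 against 0.99 to 3.52) and neutrophils (22.3 to 39.2 against 15.6 to 20.9). B cells (1132 to 1529 against 1538 to 1942), lung epithelial cells (6.76 to 25.4 against 29.6 to 42.0), macrophages and monocytes (6.34 to 13.9 against 15.6 to 31.8) and thymic epithelial cells (8.35 to 14.2 against 18.9 to 28.6) had lower marker sums. In ear skin they were higher for dendritic cells (326 to 408 against 86.5 to 158 CPM), fibroblasts (21.9 to 35 against 2.44 to 11.6), hepatocytes (7.76 to 21.6 against 0.99 to 3.52) and keratinocytes (50.2 to 52.1 against 18.3 to 24.1). Macrophages and monocytes (32.8 to 43.2 against 15.6 to 31.8), mesothelial cells (16.1 to 37.7 against 8.16 to 9.54) and neutrophils (103 to 171 against 15.6 to 20.9) had higher marker sums. B cells (304 to 645 against 1538 to 1942) and endothelial cells (60.9 to 115 against 219 to 235) had lower marker sums. In VAT they were higher for mesothelial cells (107 to 169 against 8.16 to 9.54 CPM) and neutrophils (101 to 463 against 15.6 to 20.9). Endothelial cells (60.8 to 96.4 against 219 to 235) and thymic epithelial cells (6.90 to 13.8 against 18.9 to 28.6) had lower marker sums.

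Per the series text, the DT against PBS comparison asks whether Treg cells that refilled a tissue after depletion in adult life differ from those of the control arm. In VAT the genes of the VAT Treg state did not pass the test. Pparg stood at 44.7 ± 27.9 CPM in the DT-labelled and 85.1 ± 16.2 in the PBS-labelled libraries (n = 4 each; log2 fold change -0.91 ± 0.47 SE, adjusted p = 0.718 with edgeR), Il1rl1 at 638 ± 109 and 988 ± 317 (adjusted p = 0.565), Klrg1 at 1325 ± 405 and 1924 ± 541 (adjusted p = 0.716) and Gata3 at 1571 ± 102 and 2031 ± 442 (adjusted p = 0.571). Foxp3 stood at 386 ± 48.9 and 388 ± 79.2 CPM. Of the VAT Treg list, 0 of 21 genes passed the test, also when adjusted over the list alone, and the median log2 fold change was -0.52 (camera adjusted p = 7.06e-08, adjusted p = 0.436 with an estimated correlation). edgeR called 14 of 12067 genes. Themis (chromosome 10, 28668360 to 28883818, mm10), a regulator of T cell receptor signalling, was higher in the DT-labelled arm (63.5 ± 8.00 against 17.6 ± 4.94 CPM, log2 fold change 1.86 ± 0.21 SE, edgeR adjusted p = 0.0105), with Oas3 (1.54), Gpr15 (1.38), H2-DMa (1.2) and Casp1 (0.90). Rln3 (-2.54), Nrn1 (-2.15; chromosome 13, 36725361 to 36735131), Echdc2 (-1.91), Specc1 (-1.70), Lrrn4 (-1.55), Ypel2 (-1.23), the kinase gene Lyn (-1.08; chromosome 4, 3678115 to 3813122), Pros1 (-1.06) and Coro1c (-0.72) were lower. Lrrn4 is on the mesothelial marker list and stood at 172 CPM in PBS replicate 2. PBS replicate 2 also held the lowest levels of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty of all 50 libraries (19.3, 45.7, 12.6 and 20.5 plain CPM, against at least 48.1, 65.6, 20.5 and 20.7 elsewhere). Its Xist stood at 2.59 CPM, above the other VAT libraries and below 8.52 in D49 P2 replicate 3. Without it edgeR called 1 gene here and 2239 in PBS-labelled VAT against spleen, instead of 2627. Marker sums of other cell types in the DT-labelled against the PBS-labelled libraries were higher for hepatocytes (1.71 to 3.57 against 0.20 to 1.60 CPM). Mesothelial cells (29.4 to 62.3 against 107 to 169) had lower marker sums. Summed B cell markers of the VAT libraries ran from 406 to 6326 CPM across both arms. These calls rest on single libraries, the count being 8, 1, 0, 27, 0, 2, 2 and 2 without VAT PBS replicates 1, 2, 3 and 4 and VAT DT replicates 5, 6, 7 and 8. Every named gene lost its call without VAT PBS replicate 3 and again without VAT DT replicate 5, and Themis kept it without each of the others. The lost calls had an edgeR adjusted p of 0.0554 to 0.0931 without VAT PBS replicate 1, 0.132 to 0.159 without VAT PBS replicate 2, 0.0748 to 0.165 without VAT PBS replicate 3 and 0.0582 without VAT PBS replicate 4. The p was 0.0863 to 0.232 without VAT DT replicate 5, 0.0601 to 0.113 without VAT DT replicate 6, 0.105 to 0.143 without VAT DT replicate 7 and 0.0604 to 0.147 without VAT DT replicate 8. Calls were also lost, with the edgeR or, for voom, limma adjusted p in parentheses, with limma voom for Nrn1 (0.101) and with all 32 peripheral libraries in the fit for Oas3, Gpr15, Echdc2, Specc1, Lrrn4, Lyn and Pros1 (0.0787 to 0.494). DESeq2 called 95 genes, and without the filter on low counts edgeR called 199, among them Il1rl1 (-0.63, adjusted p = 0.00101).

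**Figure D3:**
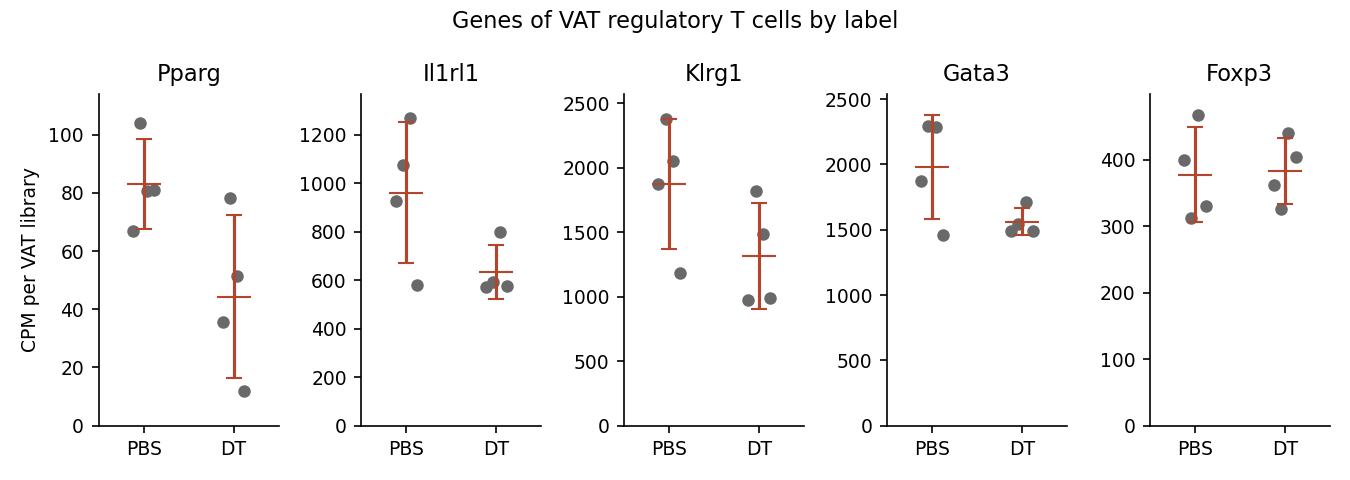
Points are CPM of 5 genes in each of the 4 PBS-labelled and 4 DT-labelled VAT libraries, and red bars are the mean and SD. Pparg lay between 11.8 and 78.3 CPM in the DT-labelled libraries and between 66.7 and 104 in the PBS-labelled ones.

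In ear skin, Ifitm3, Ifitm2 and Gbp6, which interferon induces, were higher in the DT-labelled arm, and Nrn1 and Magi1 were lower. Ifitm3 stood at 26.9 ± 17.8 CPM in the DT-labelled and 0.389 ± 0.465 in the PBS-labelled libraries (edgeR adjusted p = 0.000556), and the cytokine gene Il4 at 25 ± 24.1 and 0.615 ± 0.847. The higher genes also include Ifitm2 (2.98), the guanylate-binding gene Gbp6 (1.92), Tgtp2 (2.44), the inhibitory receptor gene Lag3 (2.17), Cxcr3 (2.11), Nkg7 (2.02), Pik3ap1 (2.22) and Spsb1 (1.80). Nrn1 went from 60.1 ± 6.08 to 8.84 ± 5.47 CPM (log2 fold change -2.79 ± 0.33 SE, edgeR adjusted p = 0.000556), and Magi1 (-2.42), Colq (-1.74), Srm (-1.72), Tff1 (-1.67), Plcb4 (-1.58), Lyn (-1.49), Polr1b (-1.41), Cdca7 (-1.36) and Slc19a1 (-1.10) were lower. Of the interferon response list, 2 of 25 genes rose, and 14 when adjusted over the list alone (median 0.67; camera adjusted p = 7.32e-16, adjusted p = 0.218 with an estimated correlation). Foxp3 stood at 372 ± 27.2 and 395 ± 38.7 CPM. edgeR called 54 genes, 35 higher and 19 lower. The count was 20, 33 and 31 without ear skin PBS replicate 1 and ear skin DT replicates 4 and 5. The calls of Ifitm3, Ifitm2, Gbp6, Lag3, Nkg7, Nrn1, Magi1 and Plcb4 held without each single library. Without PBS replicate 1 the calls of Il4, Tgtp2, Cxcr3, Spsb1, Srm, Tff1, Lyn, Polr1b, Cdca7 and Slc19a1 were lost (edgeR adjusted p = 0.133 to 0.274). Without PBS replicate 2 the calls of Il4, Cxcr3, Spsb1, Colq, Lyn, Polr1b, Cdca7 and Slc19a1 were lost (edgeR adjusted p = 0.0574 to 0.118). Without PBS replicate 3 the calls of Tgtp2, Cxcr3, Pik3ap1, Spsb1, Colq, Srm, Tff1 and Lyn were lost (edgeR adjusted p = 0.0506 to 0.0978). Without DT replicate 4 the calls of Tgtp2, Spsb1, Colq, Polr1b, Cdca7 and Slc19a1 were lost (edgeR adjusted p = 0.0738 to 0.127). Without DT replicate 5 the calls of Tgtp2, Cxcr3, Spsb1, Srm, Tff1, Polr1b, Cdca7 and Slc19a1 were lost (edgeR adjusted p = 0.0606 to 0.150). Without DT replicate 6 the calls of Pik3ap1, Spsb1, Colq, Srm, Tff1, Cdca7 and Slc19a1 were lost (edgeR adjusted p = 0.0525 to 0.144). Calls were also lost, with the edgeR or, for voom, limma adjusted p in parentheses, with limma voom for Ifitm3, Il4, Cxcr3, Spsb1, Cdca7 and Slc19a1 (0.0562 to 0.385), with a floor of 20 CPM for Cxcr3 and Lyn (0.0672 and 0.0518) and with all 32 peripheral libraries in the fit for Lag3, Cxcr3, Nkg7, Pik3ap1, Spsb1, Magi1, Colq, Srm, Tff1, Lyn, Cdca7 and Slc19a1 (0.0562 to 0.598). Marker sums of other cell types in the DT-labelled against the PBS-labelled libraries were higher for erythroid cells (4.81 to 9.12 against 2.17 to 4.46 CPM) and neutrophils (225 to 381 against 103 to 171). Mesothelial sums were 2.35 to 16.2 against 16.1 to 37.7 CPM.

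In spleen, lung and liver edgeR called 0 genes in each tissue, with 349, 413 and 519 genes at an unadjusted p under 0.05. DESeq2 called 0, 2 and 16, and limma voom with quality weights 0 in each. The liver count was 5 without liver DT replicate 5. On simulated counts with the spread of these libraries, edgeR recovered 86.0%, 92.0% and 98.0% of genes changed 4-fold and 2.0%, 6.0% and 16% of those changed 1.5-fold. The 200 changed genes had a mean of at least 10 CPM, so these shares do not cover lower genes or fewer changed genes. Foxp3 stood at 324 ± 50.0 and 242 ± 107 CPM in DT-labelled and PBS-labelled spleen, at 339.7 ± 44.0 and 340.1 ± 40.0 in lung and at 280.3 ± 20.3 and 322 ± 46.9 in liver. Gata3 had log2 fold changes of -0.08, 0.45 and 0.32, and Il1rl1 of 0.57, 0.31 and -0.13, none past the test. Naive T cell genes had medians of -0.18, -0.27 and -0.46 (camera adjusted p = 0.00628, 8.78e-06 and 4.41e-09; adjusted p = 0.637, 0.435 and 0.616 with an estimated correlation). Whether the DT effect differs between VAT and spleen was tested as an interaction, which called 3 genes, Mapkbp1 (-2.38), Lamc1 (-1.73) and Diaph3 (-3.01), the last of which lies outside the rule for named genes and was chosen after its values were seen. Pparg, near 0 CPM in spleen, and Il1rl1 (-1.21) did not pass (adjusted p = 0.885 and 0.762 with edgeR), and with the compared groups alone the count was 0. The count was 1, 14, 1, 1, 1, 1, 1, 1 and 1 without spleen PBS replicates 2 and 3, spleen DT replicates 4 and 6, VAT PBS replicates 2 and 3 and VAT DT replicates 5, 6 and 8. In this test Lamc1 was not called without spleen PBS replicate 2, spleen DT replicates 4 and 6, VAT PBS replicates 2 and 3 and VAT DT replicates 5, 6 and 8 (edgeR adjusted p = 0.234, 0.121, 0.188, 0.105, 0.0987, 0.159, 0.105 and 0.105). Calls were also lost, with the edgeR or, for voom, limma adjusted p in parentheses, with limma voom for Lamc1 (0.149) and with the compared libraries alone for Mapkbp1 and Lamc1 (0.212 and 0.763). Marker sums of other cell types in DT-labelled spleen were higher for neutrophils (23.5 to 28.5 against 15.6 to 20.9 CPM). In DT-labelled liver they were higher for macrophages and monocytes (18.2 to 57.2 against 6.34 to 13.9 CPM). Adipocytes (4.10 to 4.52 against 5.09 to 12.7) had lower marker sums. Without spleen PBS replicate 1, which stood apart, the spleen count was 0 (edgeR, 439 at an unadjusted p under 0.05).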

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

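The tests of explanations and the splits of the libraries given here and in the later parts were chosen only after the results were seen. In VAT, the only tissue with 4 libraries per arm, 8 of 58 groups of values held a library far from the other 3, and chance gives such a gap in about 1 in 20 groups. In PBS replicate 2, Lrrn4 stood at 172 CPM and the mesothelial marker sum at 169 CPM. Lrrn4 is a member of that list, so these are not 2 independent cases among the 8. This library also held the lowest levels of 4 Y-linked genes of the 50 libraries, as given above. Its Xist stood at 2.59 CPM against at most 0.856 in the other 7 VAT libraries and up to 8.52 in D49 P2 replicate 3. In PBS replicate 4, Oas3 stood at 17.2 CPM. In DT replicate 7, Il1rl1 stood at 802 CPM, Cd36 at 13 CPM, the macrophage and monocyte marker sum at 138 CPM and the fibroblast marker sum at 759 CPM. In DT replicate 8, Ypel2 stood at 21.8 CPM. Oas3, Lrrn4 and Ypel2 are among the 14 genes called in VAT.

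The D49 against D5 change differed between P2 and P1 in 55 genes, and the DT effect between VAT and spleen in 3. Chance cannot be excluded for either count. Of 30 groupings drawn for each, 2 gave a count as large for the first, the highest other being 1160, and 4 for the second, the highest other being 10. One grouping thus called many times the real count of the first, which points to a structure of the samples. In that grouping 6 of 6 P2 libraries kept their age and 2 of 6 P1 libraries did, so it still carries the age difference of P2. The draws shuffled age or arm labels within each population or tissue, so they stand for no age or DT effect at all. They do not stand for an equal effect, and so cannot decide whether chance gave the 55 or the 3 genes.

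The VAT Treg list had a median log2 fold change of -0.52 in DT-labelled VAT, with 0 genes higher and 0 lower past the test (edgeR) and 21 measured (camera adjusted p = 7.06e-08, adjusted p = 0.436 with an estimated correlation). Chance cannot be excluded, since 4 of 35 splits of the 8 libraries gave a median of log CPM differences as far from 0 as the real -0.48, the highest other being 0.61 in size. B cell RNA as the whole cause is argued against by a median of -0.45 with the B cell marker sum in the fit, the median without single libraries lying between -0.72 and -0.30 (SD 0.141). A lower VAT Treg programme in the DT-labelled arm stays open as a hypothesis, and depletion, which the labels do not show to have taken place, cannot be separated here from the receptor genotype that the series text names for the arms.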

How the results depend on the processing

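The alternatives of a floor of 20 CPM, the background covariate, leaving out D49 P2 replicates 2 and 3 together and the pooled DT effect with its voom and blocked fits, with the values they gave, were chosen only after the data were seen. Of 4611 alternative values of the 337 called named genes, 4186 kept direction and side of the threshold, 425 lost the call and 0 changed direction. Of 896 values of the 65 named genes that were not called, 826 kept both, 11 passed the threshold and 59 changed direction. With RLE size factors every count of changed genes stayed within 1.5 times. The cause of the values below was not tested. A higher floor tests fewer genes. Left-out libraries or compared groups alone leave fewer samples, yet some counts rose. The depth limits genes of few counts.

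The reported edgeR counts that moved by over 1.5 times were 2701 for P1 D12 against D5, 3491 for P1 D49 against D12, 1587 for P1 D49 against D5, 762 for P2 D12 against D5, 2196 for P2 D49 against D12, 3788 for P2 D49 against D5, 2258 for D5 P2 against P1, 6068 for D12 P2 against P1, 4318 for D49 P2 against P1, 55 for the age by progenitor interaction, 0 for spleen DT against PBS, 0 for lung DT against PBS, 0 for liver DT against PBS, 54 for ear skin DT against PBS, 14 for VAT DT against PBS, 2805 for PBS lung against spleen, 3023 for PBS liver against spleen, 4169 for PBS ear skin against spleen, 2627 for PBS VAT against spleen, 3 for the VAT against spleen DT interaction and 30 for pooled DT against PBS (edgeR called 0 in spleen, lung and liver with 349, 413 and 519 genes at an unadjusted p under 0.05). Without a filter on low counts the counts were 3492 for P2 D49 against D12, 853 for the age by progenitor interaction, 3 for spleen DT against PBS, 7 for lung DT against PBS, 39 for liver DT against PBS, 167 for ear skin DT against PBS, 199 for VAT DT against PBS, 27 for the VAT against spleen DT interaction and 104 for pooled DT against PBS. DESeq2 gave 307 for the age by progenitor interaction, 2 for lung DT against PBS, 16 for liver DT against PBS, 171 for ear skin DT against PBS, 95 for VAT DT against PBS and 11 for the VAT against spleen DT interaction. limma voom with quality weights gave 4529 for P1 D12 against D5, 3137 for P1 D49 against D5, 2042 for P2 D12 against D5, 4466 for D5 P2 against P1 and 464 for the age by progenitor interaction. limma voom without weights gave 58 for pooled DT against PBS. With a floor of 20 CPM the counts were 1508 for P1 D12 against D5, 2238 for P1 D49 against D12, 1091 for P2 D49 against D12, 2154 for P2 D49 against D5, 4024 for D12 P2 against P1, 2756 for D49 P2 against P1 and 2771 for PBS ear skin against spleen. With the background covariate the counts were 448 for P1 D12 against D5, 658 for P1 D49 against D12, 250 for P2 D49 against D12, 1357 for P2 D49 against D5, 3473 for D12 P2 against P1, 1827 for D49 P2 against P1 and 4 for the age by progenitor interaction. With the compared libraries alone the counts were 2653 for P1 D49 against D5, 1908 for P2 D12 against D5, 79 for P2 D49 against D12, 1093 for P2 D49 against D5, 4143 for D5 P2 against P1, 1220 for D49 P2 against P1, 1251 for PBS lung against spleen, 1449 for PBS liver against spleen, 2263 for PBS ear skin against spleen, 1615 for PBS VAT against spleen, 16 for the age by progenitor interaction and 0 for the VAT against spleen DT interaction (edgeR, 708 at an unadjusted p under 0.05). With all 32 peripheral libraries the counts were 25 for ear skin DT against PBS. Without D49 P2 replicates 2 and 3 the counts were 538 for P2 D49 against D12, 1779 for P2 D49 against D5, 2348 for D49 P2 against P1 and 171 for the age by progenitor interaction.

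Leaving out each library in turn gave 1006 to 1817 for P1 D12 against D5, 1029 to 1209 for P1 D49 against D5, 2 to 1243 for the age by progenitor interaction, 435 to 527 for P2 D12 against D5 and 2156 to 6035 for P2 D49 against D5. They were 1971 to 2448 for P1 D49 against D12, 703 to 5317 for P2 D49 against D12, 2805 to 6446 for D49 P2 against P1, 0 to 5 for liver DT against PBS and 20 to 48 for ear skin DT against PBS. Further values were 0 to 27 for VAT DT against PBS, 1979 to 3246 for PBS liver against spleen, 1 to 14 for the VAT against spleen DT interaction and 14 to 36 for pooled DT against PBS. Where an arm keeps few libraries, they are assumed to vary like the other groups in the fit.

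Gene lists called with the preset correlation numbered 51 for age, 29 for P2 against P1, 46 for DT against PBS and 47 for tissue against spleen. With an estimated correlation they were 13 for age, 8 for P2 against P1, 0 for DT against PBS and 21 for tissue against spleen, and fry called 0 for DT against PBS. By the rule that each same-numbered correlation be over 0.1, replicate numbers paired the libraries only in PBS ear skin against spleen among the comparisons made. DT liver and spleen, which only the pooled DT effect holds together, also met it. In PBS liver and VAT against spleen, 2 of 3 same-numbered pairs were over 0.1, up to 0.271 and 0.165, so pairing stays open there. Different numbers reached 0.241 in PBS lung against spleen. Over all same-numbered pairs of each kind of comparison, 0 of 18 (age), 0 of 9 (P2 against P1) and 10 of 23 (tissue against spleen) had a correlation over 0.1, and 4, 4 and 12 correlated best with their own number. With the replicate number as a block, ear skin against spleen had 4103 calls against 4169, and no named gene changed its call there, while 2 marker lists passed with the block alone. Elsewhere the blocked count was 14 for the age by progenitor interaction, and no other planned count of genes moved by over 1.5 times. The replicate number as a random block within each arm gave 55 for pooled DT against PBS, close to voom without the block.

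Values of genes that were not called and changed direction were these. Without a filter the log2 fold changes were Il2ra 0.038 (P1 D49 against D5), Foxp3 -0.0334 (the age by progenitor interaction), Foxp3 0.0054 (lung DT against PBS), Il2ra 0.0026 (lung DT against PBS), Klrg1 0.0478 (lung DT against PBS), Foxp3 -0.0039 (VAT DT against PBS) and Il2ra -0.01 (PBS ear skin against spleen). With voom the log2 fold changes were Il2ra 0.0258 (P1 D49 against D5), Klrg1 0.13 (spleen DT against PBS), Gata3 0.20 (spleen DT against PBS), Klrg1 0.0829 (lung DT against PBS), Pparg 0.0261 (liver DT against PBS) and Cd36 -1.11 (the VAT against spleen DT interaction). With the 20 CPM floor the log2 fold change was Il2ra 0.0042 (P1 D49 against D5). With the covariate the log2 fold change was Il2ra -0.0064 (P1 D12 against D5). With the compared libraries alone the log2 fold change was Il2ra 0.0089 (P1 D49 against D5). With all 32 libraries the log2 fold changes were Klrg1 0.0408 (lung DT against PBS) and Foxp3 -0.0049 (VAT DT against PBS). With the block the log2 fold change was Cd36 -2.30 (the VAT against spleen DT interaction). Over left-out libraries such genes ran -0.0959 to 0.12 for Il2ra (P1 D49 against D5), -0.43 to 0.0211 for Il2ra (spleen DT against PBS), -0.50 to 0.65 for Klrg1 (spleen DT against PBS), -0.28 to 0.22 for Gata3 (spleen DT against PBS) and -0.50 to 0.12 for Areg (spleen DT against PBS). They were -0.13 to 0.0702 for Foxp3 (lung DT against PBS), -0.11 to 0.0488 for Il2ra (lung DT against PBS), -0.14 to 0.24 for Klrg1 (lung DT against PBS), -0.0722 to 0.18 for Ikzf2 (lung DT against PBS) and -0.0392 to 0.17 for Il2ra (liver DT against PBS). Further values were -0.70 to 0.50 for Pparg (liver DT against PBS), -0.74 to 0.23 for Il1rl1 (liver DT against PBS), -0.52 to 0.10 for Klrg1 (liver DT against PBS), -0.036 to 0.26 for Areg (liver DT against PBS) and -0.084 to 0.0668 for Ikzf2 (liver DT against PBS). Other values were -0.13 to 0.0296 for Foxp3 (ear skin DT against PBS), -0.0414 to 0.13 for Pparg (ear skin DT against PBS), -0.26 to 0.13 for Il1rl1 (ear skin DT against PBS), -0.0754 to 0.15 for Foxp3 (VAT DT against PBS) and -0.11 to 3.39 for Cd36 (PBS lung against spleen). The rest were -0.81 to 2.48 for Cd36 (PBS liver against spleen), -0.0632 to 0.43 for Il2ra (PBS ear skin against spleen), -0.53 to 0.055 for Il2ra (the VAT against spleen DT interaction), -0.76 to 0.0014 for Areg (the VAT against spleen DT interaction) and -2.37 to 2.51 for Cd36 (the VAT against spleen DT interaction).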

Other observations

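The hypotheses in this part and their tests were chosen only after the results were seen, while the gene lists were fixed before. Genes of NF-kB signalling, which follow inflammatory and receptor signals, were higher than in spleen in all 16 of 16 measured genes in lung and 14 in liver (16 and 15 when adjusted over the list alone; adjusted p = 0.00492 and 0.00728 with an estimated correlation). The NF-kB inhibitor gene Tnfaip3 stood at 2048 ± 321 CPM in lung, 3028 ± 1082 in liver and 94.2 ± 22.9 in spleen (SD, n = 3 each). T cell receptor response genes were higher in liver in 11 of 19 and lower in 2 (adjusted p = 0.0312 with an estimated correlation; 13 and 3 when adjusted over the list alone), with Nr4a1 at 4.60 ± 0.41 SE and Dusp5 at 3.53 ± 0.31 SE on the log2 scale. Genes that respond to tissue digestion were also higher than in spleen, 10 of 20 in lung, 15 in liver, 12 in ear skin and 15 in VAT (adjusted p = 0.0998, 0.0128, 0.0970 and 0.00526 with an estimated correlation). At D5 the receptor response list was lower in P2 than P1 in 11 of 19 and higher in 1 (adjusted p = 0.0393 with an estimated correlation; 11 and 1 when adjusted over the list alone), with Tnfrsf9 going from 494 ± 42.2 to 137 ± 27.2 CPM between P1 and P2. In VAT, 8 of 23 genes of lipid handling were higher than in spleen and 1 was lower (8 and 2 when adjusted over the list alone; adjusted p = 0.0488 with an estimated correlation). The lipid droplet coat gene Plin2 stood at 553 ± 212 against 36.6 ± 17.5 CPM (SD, n = 4 and 3), the triglyceride synthesis gene Dgat1 at 555 ± 273 against 57.0 ± 13.9, and Cpt1a, which takes fatty acids into mitochondria, at 212 ± 38.0 against 61.8 ± 11.3. The lysosomal lipase gene Lipa was lower (-1.22). Glycolysis genes were higher than in spleen in 12 of 16 in ear skin and 9 in liver (12 and 11 when adjusted over the list alone; adjusted p = 0.0380 and 0.0315 with an estimated correlation), with Tpi1 at 2.41 ± 0.22 SE in ear skin.

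With DT against PBS taken as 1 effect over the 5 tissues, chosen after seeing the data, edgeR called 30 of 17731 genes, 19 higher and 11 lower, with 1086 at an unadjusted p under 0.05. Litaf (1.02), Ifitm2 (1.52), the inflammatory caspase genes Casp4 (0.59) and Casp1 (0.51), H2-DMa (0.67), Themis (0.90), the ectonucleotidase gene Entpd1 (0.51) and the growth factor gene Csf1 (0.91) were higher, and Adam12 (-1.87), Rln3 (-1.55), Nrn1 (-1.37), Magi1 (-1.79) and Tff1 (-1.70) lower (log2 fold changes, edgeR adjusted p = 0.000357 for Litaf to 0.0492 for Magi1). These genes were chosen after their values were seen. The mean neutrophil marker sum was higher in the DT-labelled arm in all 5 tissues, at 26.1 ± 2.47 against 17.5 ± 2.94 CPM in spleen, 37.2 ± 12.8 against 16.2 ± 13.5 in lung, 54.2 ± 35.5 against 29.1 ± 8.90 in liver, 297 ± 78.9 against 146 ± 37.5 in ear skin (SD, n = 3 each) and 290.1 ± 81.8 against 265 ± 158 in VAT (n = 4 each). The libraries of the arms overlap in lung, liver and VAT, and the only other marker list with a mean on the same side in all 5 tissues was the thymic epithelial one, lower in the DT-labelled arm. Without VAT PBS replicate 2, the library with the lowest Y-linked levels, the pooled count was 25. Libraries of different tissues that may come from the same mouse were treated as independent, so these p-values may be too small. Same-numbered libraries of 2 pairs of groups in this fit deviate together, PBS-labelled ear skin and spleen (0.101 to 0.109) and DT-labelled liver and spleen (correlations of 0.104 to 0.116, against -0.133 to 0.0199 between different numbers). The 2 arms of a tissue share no number, so a fixed block would take up the DT effect. With the number within each arm as a random block, also chosen after seeing the data, limma voom called 55 genes, against 58 without the block (consensus correlation 0.00834), and 29 of the 30 edgeR genes were among the 55, the genes named here included. That block takes each arm and number as 1 mouse, which the labels do not state. DT-labelled spleen and VAT share 2 numbers, whose libraries had correlations of 0.0194 and -0.112. On simulated counts with a strong spread shared within a block, the block cut false calls but did not remove them. The similar counts thus do not show that libraries of different tissues are independent. With single libraries left out in turn, the count was 16, 19, 19, 17, 16, 19, 14 and 17 without spleen DT replicate 6, lung PBS replicate 1, lung DT replicate 5, liver PBS replicates 1 and 2, liver DT replicate 4 and ear skin PBS replicates 1 and 2.

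D12 P1 libraries and D49 P2 replicates 2 and 3 held more detected genes than the other 13 thymus libraries. Library size is argued against, since at one thinned depth the lowest of the 5 libraries still held 5420 more genes than the highest of the other 13. Macrophage RNA is argued against for D12 P1, whose highest marker sum was 0.212 of the highest of the other 13, and stays open for D49 P2, where the lower of replicates 2 and 3 was at 2.18 times that value. Reads spread over genes that T cells do not use may be part of the pattern, because the summed CPM of 1471 olfactory and vomeronasal receptor genes in the lowest of the 5 was 1.71 times the highest of the other 13. Whether those reads come from DNA, from amplification or from real transcripts was not tested, and age and population stay open as biological explanations.

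Themis was higher and Nrn1 and Lyn were lower in the DT-labelled arm of both VAT and ear skin, 3 genes against 0.0282 expected among 11269 tested in both. Chance overlap of independent lists is argued against by a permutation p of 1e-05, the smallest that 100000 permutations can give, with genes treated as independent, and X-linked genes were not more frequent among those called (1 of 61 called and 326 of all 11116 tested genes with a known chromosome, Fisher exact test, two-sided p = 1), and none of the 3 lies on the X chromosome, while an effect of an X-linked allele on other chromosomes stays open. The direction was the same in 8 of 9 comparisons in spleen, lung and liver, which leaves open whether the difference is present in every tissue. In VAT Themis was not called without VAT PBS replicate 3 and VAT DT replicate 5 (edgeR adjusted p = 0.0748 and 0.0863), Nrn1 was not called without VAT PBS replicates 2 and 3 and VAT DT replicates 5, 6, 7 and 8 (edgeR adjusted p = 0.132, 0.111, 0.184, 0.0973, 0.105 and 0.121) and Lyn was not called without VAT PBS replicates 2 and 3 and VAT DT replicates 5, 6, 7 and 8 (edgeR adjusted p = 0.132, 0.119, 0.184, 0.0813, 0.105 and 0.121), and in ear skin Lyn was not called without ear skin PBS replicates 1, 2 and 3 (edgeR adjusted p = 0.235, 0.114 and 0.0519). VAT and ear skin libraries may come from the same mice.

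With 3 libraries against 3 there are 10 splits of the same libraries, too few for a share under 0.05, and the following pairs give the real count and the highest of the other splits. For P1 they were 2701 and 0 at D12 against D5, 3491 and 0 at D49 against D12, and 1587 and 0 at D49 against D5. For P2, in the same order, they were 762 and 0, 2196 and 4, and 3788 and 0. For P2 against P1 they were 2258 and 0 at D5, 6068 and 0 at D12, and 4318 and 2 at D49. For DT against PBS they were 54 and 0 in ear skin. The real DT counts in spleen, lung and liver are 0, so all 10 splits are as large by construction and say nothing of them, the highest others being 0, 1 and 0 (edgeR, with 349, 413 and 519 genes at an unadjusted p under 0.05, DESeq2 calling 0, 2 and 16 and voom 0, 0 and 0). Against spleen they were 2805 and 129 in lung, 3023 and 12 in liver, and 4169 and 8 in ear skin. The real split of ear skin and spleen parts all 3 same-numbered pairs, and the other splits that part 3 called at most 1, while those that part 1 called up to 8. VAT against spleen had 1 of 35 splits as large, the least possible (real 2627, highest other 1472). Chance cannot be excluded for DT against PBS in VAT (2 of 35, real 14, highest other 14). For the gene lists called with the preset correlation, 1 of 30 groupings, the real one, gave as many calls in each family. That is the smallest share that 30 groupings can give, and it concerns only the counts under this preset. Shuffled libraries gave nearly as many, with real and highest other counts of 51 and 43 for age, 29 and 25 for P2 against P1, 46 and 41 for DT against PBS, and 47 and 40 for tissue against spleen. A single list call under that preset is thus weak evidence. For DT against PBS, camera with an estimated correlation called 0 lists and fry 0 (limma, with 10 and 9 of 92 at an unadjusted p under 0.05), so the preset calls do not show a change of any list in that comparison.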
